A study of Mus musculus with 6 samples.

How the data were processed

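RNA sequencing had been carried out on MC38 cells, a mouse colorectal cancer line. Per the labels, all 6 samples had been treated with interferon gamma at 100 ng per mL for 24 hours. Total RNA was isolated with TRIzol and purified on RNeasy columns, and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The kit is not stated to mark the strand, so reads of overlapping genes on opposite strands cannot be told apart in these values. Groups were taken from the sample titles: 3 control samples and 3 samples with SRC-1 (gene Ncoa1) knocked out. The genotype labels of knockout replicates 2 and 3 read KOSRC-2 and KOSRC-3, whereas all 3 titles read KOSRC-1. SRC-2 and SRC-3 are also names of the paralogs Ncoa2 and Ncoa3, so by themselves those labels may be replicate numbers or other targets, and the titles were followed. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

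The deposited table lists 16583 genes with 3 values per sample. Per the file headers these are read counts, FPKM (fragments scaled by transcript length and depth) and TPM (transcript abundances scaled to a fixed sum). The deposited read counts are expected counts, since only 88.9% of them are whole numbers. The deposited FPKM and TPM were made by the authors, and the program that made the 3 kinds of value is not given in the sources used here. The submitters' processing notes name HISAT2, StringTie and SAMtools, with no versions, and the genome build GRCm38.p6. The group averages in the same table were not used. None of the 13 mitochondrially encoded mRNAs fixed as a list is among the genes of the table used here, so no check of RNA quality could be based on them.

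The expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15, smallest group 3), which left 11656 genes. The comparison of knockout with control was made with edgeR 4.0.16 in R 4.3.3, with TMM scaling and the robust quasi-likelihood test, two-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene is described as called, risen or fallen when its adjusted p was under 0.05. Adjusted p-values in the text come from this test unless another is named. Levels are CPM (counts scaled to library size) with TMM factors, given as mean ± SD over 3 libraries, and standard errors (SE) belong to log2 fold changes, knockout minus control. Intervals for genes with few counts cover 95% of counting error only. For a gene with no count in a group, the limit was set at 3 counts over the group.

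The 25 gene lists, their members and the rule for named genes were fixed before the data were examined. A list needed 3 measured members, which 22 lists had. Lists were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone where the 2 differ. Under the rule, Ncoa1, Ncoa2, Ncoa3, Cd274, Irf1 and Itch are always named. So are the 10 called genes with the largest rise and the 10 with the largest fall, among those with no overlap between the groups and at least 5 CPM in the higher group, leaving out unnamed gene models and pseudogenes. From each list, up to 3 called members with the smallest adjusted p are named, or the member with the smallest p where none is called. This gave 86 genes, some of which are not reported here. Members that make up a small count of a list, and genes at 3 or fewer counts in the knockout, are also named, and these were chosen after their values were seen.

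Gene coordinates are from the RefSeq annotation of GRCm38.p6, the build in the submitters' processing notes, and are 1-based. Of the 16583 gene identifiers, 16531 matched it and 16501 had the same symbol. Transcript length and GC content, used in a check, were known for 97.1% of the tested genes.

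Totals ran from 16329459 to 17207625 expected counts per library. The tests were checked on simulated counts with the means and library sizes of these samples. In the simulated comparison of 3 against 3, over 11542 genes, edgeR recovered 49% of 100 genes changed by 1.5-fold and 95% of 100 genes changed by 2-fold, and 5.52% of its calls were false. DESeq2 recovered 68% and 96% with 17.5% of calls false. Limma on log2(TPM + 1), over 10792 genes, recovered 45% and 95% with 2.67% false. A planted list had an adjusted p of 4.5e-32 by camera, 0.00407 with an estimated correlation and 0.00017 by fry, and none of 24 random lists was called by any of the 3 (0 of 24). The simulated genes varied independently of each other. The check therefore cannot show how often a list is called wrongly when its members vary together.

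Alternatives were RLE and upper-quartile scaling, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(FPKM + 1), the replicate number as a block, each library left out in turn, camera without weights, camera with an estimated correlation, and fry. Limma used genes at 1 or more TPM or FPKM in at least 3 samples. A correction for transcript length and GC content, made per library as offsets, and limma on log2(TPM + 0.1) were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.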

Results

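The study asked how SRC-1, a nuclear receptor coactivator encoded by Ncoa1, raises the expression of the immune checkpoint ligand PD-L1. Transcriptomes were compared between 3 control and 3 SRC-1 knockout samples of MC38 mouse colorectal cancer cells. All 6 samples had received interferon gamma (100 ng per mL, 24 hours), and no untreated samples were analysed here, so the values describe cells already stimulated. The libraries held 17061954, 17045286 and 16862043 expected counts in controls 1, 2 and 3, and 16329459, 17207625 and 16739016 in knockouts 1, 2 and 3.

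The targeted gene was examined first. Ncoa1 (gene 17977, chromosome 12, 4247362 to 4477206) stood at 18.2, 18.5 and 18.0 CPM in the controls and at 16.7, 10.1 and 16.1 CPM in the libraries labelled knockout. Every knockout library was below every control, but the difference did not pass the test (log2 fold change -0.35, SE 0.184, 95% interval -0.78 to 0.08, adjusted p = 0.179). With library trends in transcript length and GC content removed, the change was -0.45 with an adjusted p of 0.00478. Without knockout 2 it was -0.15 with an adjusted p of 0.108. Ncoa1 mRNA was thus still counted in each of them (mean 1.27-fold lower), and its level does not by itself check the labels, so "knockout" below refers to the label. Its paralogs gave no called difference. Ncoa2 was at 38.8 ± 1.29 CPM in controls and 48.7 ± 18.8 in knockouts (adjusted p = 0.39), and Ncoa3 was at 69.0 ± 0.918 and 67.3 ± 9.11 (adjusted p = 0.818), with n = 3 in each group for these edgeR tests. The genotype labels of knockouts 2 and 3, unlike their titles, carry the names SRC-2 and SRC-3, which Ncoa2 and Ncoa3 also bear. Across genes, knockouts 1 and 3 correlated at 0.996 in log CPM, and the controls with each other at 0.994 to 0.995. Knockouts 1 and 3 were thus as alike as control replicates, which argues against different targets in these 2 libraries. Ncoa2 was at 27.1 CPM in knockout 2, below each control (37.4 to 39.9), and at 60.8 and 58.3 in knockouts 1 and 3, whereas Ncoa3 was at 73.4 CPM in knockout 3 and not below the controls. Without knockout 2, Ncoa2 was higher by 0.62 on the log2 scale (adjusted p = 7.54e-10). The sign of the Ncoa3 change turned without knockout 2 (0.07) and in limma on TPM or FPKM, and with the length and GC trends removed Ncoa3 was lower (-0.14, adjusted p = 0.0443). With those trends removed it was below each control (70.5 to 72.3 CPM) in all 3 knockouts, at 62.9, 65.0 and 66.7 CPM in knockouts 1, 2 and 3.

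Cd274, which encodes PD-L1, was 2.41-fold lower in the knockout. It fell from 411 ± 37.1 CPM to 170 ± 3.90 CPM (SD, n = 3 each; log2 fold change -1.27, SE 0.0866, edgeR adjusted p = 9.86e-05). Cd274 is gene 60533 on chromosome 19, from 29362107 to 29388095. Irf1, an interferon-induced transcription factor, fell from 1133 ± 35.7 to 657 ± 61.2 CPM (1.72-fold lower, log2 fold change -0.79, SE 0.0923, edgeR adjusted p = 0.000882). Irf1 is gene 16362 on chromosome 11, from 53770014 to 53778374. Itch, a ubiquitin ligase, stood at 70.05 ± 2.96 CPM in controls and 75.5 ± 20.5 in knockouts (log2 fold change 0.11, SE 0.194, adjusted p = 0.691). Its estimate depended on single libraries, being 0.32 without knockout 2 (adjusted p = 7.64e-06) and -0.02 without knockout 1.

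**Figure D1:**
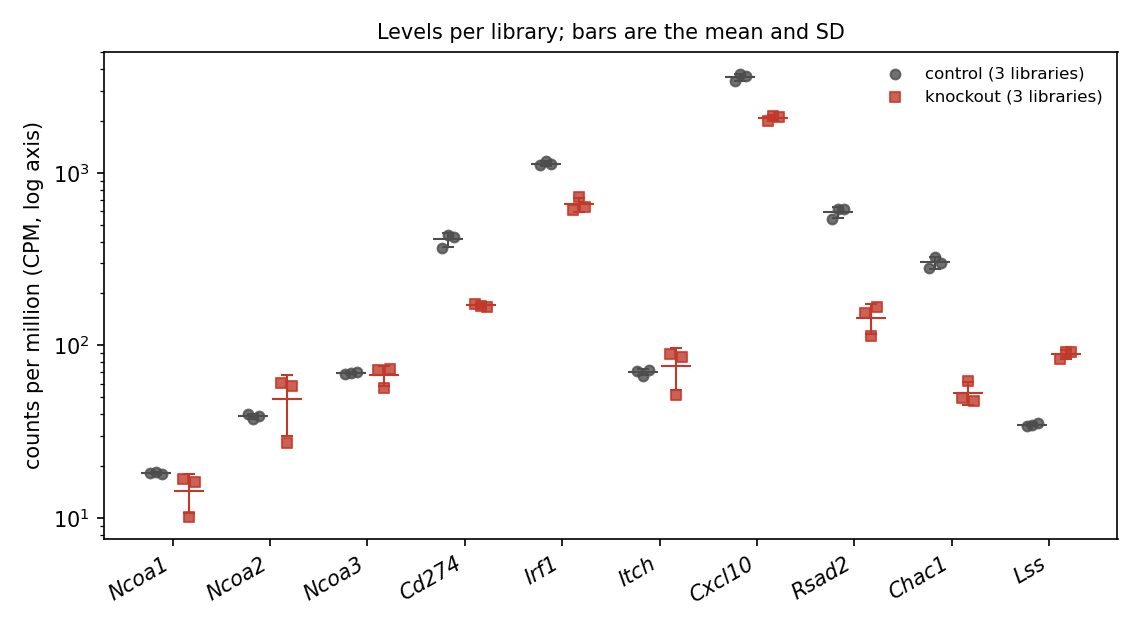
Levels of 10 genes in CPM on a log axis; grey circles are the 3 control libraries, red squares the 3 knockout libraries, and bars the mean and SD. Cd274 lies near 411 CPM in controls and 170 CPM in knockouts with no overlap, while the lowest knockout value of Ncoa1, 10.1 CPM, belongs to knockout 2.

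Across the transcriptome, 4157 of 11656 tested genes were called between knockout and control, 1999 higher and 2158 lower in the knockout. Of these, 317 were at least 2-fold higher and 513 at least 2-fold lower. The 3 values of one group all lay above those of the other in 5986 genes, or 51.4% of those tested, against 10% by chance. On the first principal component, with 73.4% of the variance, all controls lay at -31.6 or lower and all knockouts at 27.4 or higher. The second, with 17.7%, set knockout 2 (-34.5) apart from knockouts 1 (17.1) and 3 (12.4). Knockout 2 correlated with knockouts 1 and 3 at 0.978 and 0.981 in log CPM across genes, whereas those 2 correlated at 0.996 and the controls at 0.994 to 0.995. Without knockout 2 the test called 8208 of 11793 genes, 4075 higher and 4133 lower, including 99.8% of the 4157. Without control 1, 2 or 3 it called 2576, 2406 or 2409 genes, and with the length and GC trends removed it called 6239, of which 3474 were higher.

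**Figure D2:**
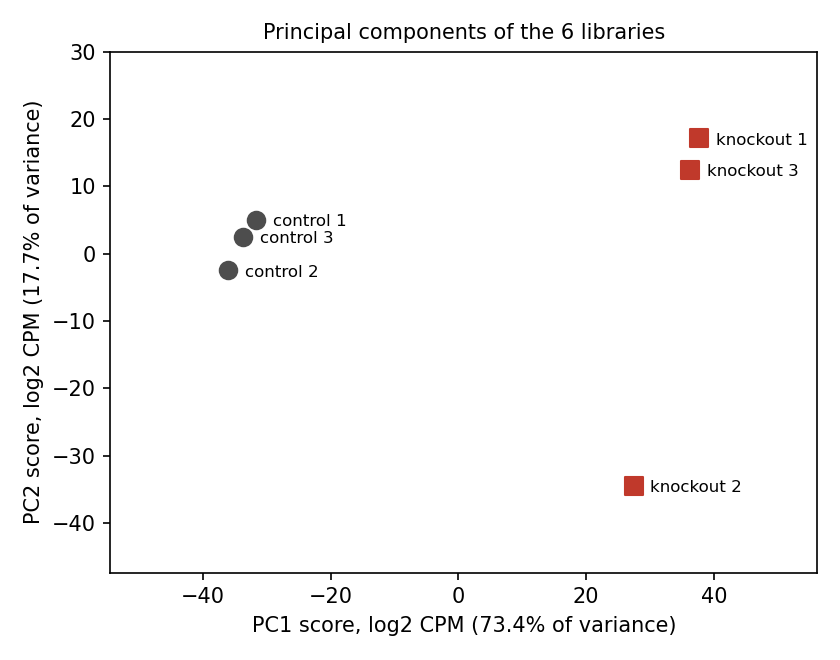
Scores of the 6 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; grey circles are controls and red squares knockouts. The groups part along the first axis, and knockout 2 lies at -34.5 on the second.

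The genes with the largest rises came from several kinds of protein. Scn3a, a voltage-gated sodium channel subunit, rose 8.89-fold from 1.94 ± 0.796 to 17.3 ± 7.30 CPM (n = 3 each, edgeR adjusted p = 0.00167). Cbr2, a carbonyl reductase, rose 8.27-fold, the tetraspanin Tspan7 rose 7.66-fold and Sulf2, an extracellular sulfatase, rose 7.16-fold. Armcx4, the collagen gene Col12a1, the lipase inhibitor Angptl4, the dystrophin gene Dmd and Abi3bp rose 5.07-fold to 6.91-fold. Pik3r1, which encodes the regulatory p85 subunit of PI3-kinase, was the most abundant of these, rising 4.91-fold from 18.6 ± 1.53 to 91.1 ± 18.6 CPM (SE 0.166, adjusted p = 0.00014).

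The largest falls were nearly complete. Mageb4, a member of the MAGE family on the X chromosome (86250256 to 86256219), had 474 counts in the controls together and 0 in the knockouts, and was at least 156-fold lower against a limit of 3 counts over the group. Arhgap6 had 480 counts against 2 (237-fold lower, counting interval 65.3 to 1964). Lin7b had 436 counts against 3 (144-fold lower, 48.8 to 699) and Tspan6 had 329 against 3 (108-fold lower, 36.8 to 528). Eml2 had 719 counts against 4 (178-fold lower, 69.1 to 654). The junction gene Cgnl1, the potassium channel Kcnh2 and the retinal dehydrogenase Aldh1a1 were 34.7-fold to 77.6-fold lower by counts. Cdh2, encoding N-cadherin, fell 25.2-fold from 17.2 ± 0.2004 to 0.674 ± 0.278 CPM.

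The interferon gamma pathway changed in part. Of 18 measured genes of receptor and JAK-STAT-IRF signalling, 6 rose, 5 fell and 7 were not called (camera adjusted p = 0.786; the median log2 change was 0.16 and the mean 0.03). Tyk2, a Janus kinase, rose 1.56-fold, whereas Irf9, the DNA-binding subunit of the ISGF3 complex, fell from 165 ± 8.57 to 114 ± 2.69 CPM. Of 24 interferon gamma induced GTPases and effectors, 3 rose, 6 fell and 15 were not called. Camera gave this list an adjusted p of 0.987, with a median of 0.06 and a mean of -0.10. Wars, the cytosolic tryptophanyl-tRNA synthetase, fell 3.02-fold (log2 fold change -1.59, SE 0.107, adjusted p = 0.000104). Other cytosolic tRNA synthetases, in a set of ATF4 targets described below that does not hold Wars, were also lower. They ran from -0.86 (Gars) to -0.23 (Mars1, not called). Whether the fall of Wars belongs to that pattern or to the interferon pathway was not tested. The adhesion molecule Icam1 fell 2.03-fold and the chemokine Cxcl10 fell from 3594 ± 164 to 2084 ± 70.4 CPM. The 3 that rose were Nos2 (0.53), Ifi47 (0.36) and Ubd (0.72 on the log2 scale). The balance of calls turned in the alternatives. Without knockout 2, where most tested genes were called, 13 of the 24 rose and 7 fell (camera adjusted p = 0.404). With the length and GC trends removed, 11 rose and 6 fell (camera adjusted p = 0.688).

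Type I interferon stimulated genes were mostly lower. Of 30 measured, 18 fell, 11 were not called and 1, Ifitm2, rose, and 19 fell when adjusted over the list alone. The list was lower by camera (adjusted p = 2.71e-05; adjusted p = 0.335 with an estimated correlation). Oasl1 fell 6.01-fold from 75.2 ± 12.9 to 12.5 ± 2.44 CPM, and the antiviral gene Rsad2 fell 4.09-fold from 592 ± 44.2 to 145 ± 28.4 CPM (SE 0.154, adjusted p = 0.000169). Usp18, a protease that removes ISG15 from proteins, fell 2.16-fold.

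Antigen presentation genes gave few calls. Of 23 MHC class I genes, 3 rose, 0 fell and 20 were not called (camera adjusted p = 0.786), and 1 rose when adjusted over the list alone. Tapbp, the tapasin gene, rose 1.38-fold from 758 ± 36.7 to 1046 ± 12.4 CPM, with Erap1 at 1.45-fold and Calr at 1.26-fold, both calls that were lost when any 1 control was left out. The members lay a median of 0.28 higher in knockout 2 than in knockouts 1 and 3 on the log2 scale. The calls went opposite ways in the alternatives, with 6 risen and 13 fallen without knockout 2 (camera adjusted p = 0.441) and 10 risen and 1 fallen with the length and GC trends removed (camera adjusted p = 0.238). Of 7 measured MHC class II genes, 0 rose, 2 fell and 5 were not called (camera adjusted p = 0.586). Cd74, the invariant chain, went from 5.17 ± 0.957 to 1.495 ± 0.488 CPM, and the protease gene Lgmn fell 1.45-fold.

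Among 9 measured immune checkpoint ligands, 4 rose, 3 fell and 2 were not called (camera adjusted p = 0.987; median 0.23, mean -0.01). Beside Cd274, Pvr, a ligand of TIGIT, fell 2.02-fold from 123 ± 6.93 to 60.8 ± 2.15 CPM, whereas Icosl, a ligand of ICOS, rose 2.35-fold from 4.42 ± 0.403 to 10.4 ± 1.86 CPM. Of 22 factors known to affect PD-L1 protein stability, 2 rose, 0 fell and 20 were not called (camera adjusted p = 0.236), and 1 rose when adjusted over the list alone. The risen genes were the glycosyltransferase B3gnt3 (1.33-fold) and the ubiquitin ligase Nedd4 (1.38-fold), and the Nedd4 call was lost when any 1 control was left out. Without knockout 2, where most tested genes were called, 14 of the 22 rose and 3 fell (camera adjusted p = 0.0705), and with the length and GC trends removed 5 rose and 0 fell (camera adjusted p = 0.392).

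Of 18 p160 coactivators and partner coregulators, 2 rose, 0 fell and 16 were not called (camera adjusted p = 0.544). The acetyltransferase genes Crebbp and Kat2b rose 1.67-fold and 1.84-fold. Crebbp lies on chromosome 16, where the median gene was 0.24 higher on the log2 scale. Its own change was larger (0.74), and how much of it that shift accounts for was not tested. Members of this list lay a median of 0.45 lower in knockout 2 than in knockouts 1 and 3, and without it 9 rose and 3 fell (camera adjusted p = 0.107), while with the length and GC trends removed 5 rose and 3 fell (camera adjusted p = 0.795). Nuclear receptors split, with 5 of 20 higher, 3 lower and 12 not called (camera adjusted p = 0.987; median 0.05, mean -0.25). More were lower in the alternatives. Without knockout 2, 6 were higher and 8 lower (camera adjusted p = 0.857). With the length and GC trends removed, 5 were higher and 8 lower (camera adjusted p = 0.795). The vitamin D receptor gene Vdr rose 2.62-fold from 7.88 ± 0.367 to 20.6 ± 1.67 CPM and the thyroid hormone receptor gene Thra rose 1.67-fold. Of 10 glucocorticoid receptor targets, 1 rose (Cebpd), 6 fell and 3 were not called, with 2 risen when adjusted over the list alone (camera adjusted p = 0.373). Per1, Klf9 and Tsc22d3 fell 1.62-fold, 2.09-fold and 1.34-fold.

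Cytokine genes moved both ways, with 3 of 16 higher, 4 lower and 9 not called (camera adjusted p = 0.987). The chemokine Cx3cl1 rose 3.48-fold from 22.6 ± 0.896 to 78.8 ± 2.78 CPM (SE 0.0789, adjusted p = 2.43e-05). Lif fell 1.90-fold and Il33 fell 1.84-fold. Of 15 NF-kB targets, 1 rose (Nfkbiz), 7 fell and 7 were not called, with 2 risen when adjusted over the list alone. The list was lower by camera (adjusted p = 0.0416; adjusted p = 0.231 with an estimated correlation), and without knockout 2 its adjusted p was 0.0705. Nfkbie, an NF-kB inhibitor, fell 2.16-fold, Traf1 fell 2.05-fold and Birc3 fell 1.40-fold.

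The most uniform shift was in lipid synthesis. All 23 measured genes of cholesterol and fatty acid synthesis rose, with a median log2 fold change of 1.002 (camera adjusted p = 1.75e-14; adjusted p = 0.166 with an estimated correlation). Lss, the lanosterol synthase gene, rose 2.55-fold from 34.8 ± 0.660 to 88.8 ± 4.88 CPM (SE 0.0781, adjusted p = 5.63e-05), and Cyp51, the lanosterol demethylase gene, rose 2.36-fold. Genes of hypoxia and glycolysis were also higher, with 11 of 18 risen, 2 fallen (Ndrg1 and Pfkp) and 5 not called (camera adjusted p = 0.000713; adjusted p = 0.166 with an estimated correlation). The mitophagy receptor gene Bnip3 rose 2.32-fold, the phosphofructokinase gene Pfkl rose 2.13-fold and the collagen prolyl hydroxylase gene P4ha1 rose 1.59-fold.

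Stress response genes were lower. Of 14 genes of the unfolded protein and integrated stress response, 0 rose, 10 fell and 4 were not called (median -0.81; camera adjusted p = 4.25e-05; adjusted p = 0.231 with an estimated correlation). Chac1, a glutathione-degrading enzyme, fell 5.68-fold from 302 ± 23.6 to 53.3 ± 8.02 CPM (SE 0.126, adjusted p = 4.05e-05). The pseudokinase gene Trib3 fell 4.09-fold and Herpud1, a gene of endoplasmic reticulum-associated degradation, fell 2.24-fold. Members of this list lay a median of 0.28 higher in knockout 2 than in knockouts 1 and 3. Of 20 p53 targets, 3 rose (Sesn1, Ei24 and Fas), 9 fell and 8 were not called, with 10 fallen when adjusted over the list alone. The list was lower by camera (adjusted p = 0.0204; adjusted p = 0.231 with an estimated correlation). Gadd45a, a growth arrest gene, fell 9.003-fold from 264 ± 12.9 to 29.3 ± 0.968 CPM (SE 0.0792, adjusted p = 2.63e-06), the kinase gene Plk2 fell 2.96-fold and Sesn2 fell 2.20-fold. Of 13 immediate early and heat shock genes, 5 rose, 6 fell and 2 were not called (camera adjusted p = 0.544). The transcription factor genes Atf3 and Egr1 fell 5.52-fold and 3.34-fold, whereas the heat shock gene Hspa1b rose 3.61-fold. Hspa1b has a near-identical neighbour, Hspa1a, and its value is uncertain for that reason.

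Cell cycle genes were somewhat higher, with 11 of 28 risen, 1 fallen (Mcm2) and 16 not called (median 0.14; camera adjusted p = 0.00518; adjusted p = 0.343 with an estimated correlation). Top2a rose 1.54-fold from 490 ± 7.12 to 754 ± 27.3 CPM, Ccna2 rose 1.36-fold and the mitotic kinase gene Plk1 rose 1.66-fold. Wnt targets were split, with 3 of 12 higher, 2 lower and 7 not called (camera adjusted p = 0.851). Myc fell 2.69-fold from 628 ± 37.3 to 233 ± 3.32 CPM (SE 0.0764, adjusted p = 4.42e-05) and the receptor gene Ephb2 fell 4.55-fold, while Rnf43 rose 2.16-fold.

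Mesenchymal and extracellular matrix genes went both ways, with 9 of 21 higher, 4 lower and 8 not called, and 10 higher when adjusted over the list alone (camera adjusted p = 0.206; median 0.26, mean -0.11). Spp1, encoding osteopontin, fell 13.7-fold from 102 ± 2.27 to 7.47 ± 0.184 CPM (SE 0.0819, adjusted p = 2.33e-06), and Mmp9 rose 2.18-fold. Of 5 measured stromal and endothelial markers, 0 rose, 4 fell and 1 (Pdgfra) was not called (camera adjusted p = 0.000407; adjusted p = 0.231 with an estimated correlation). The collagen gene Col6a3 fell 20.9-fold from 204 ± 0.374 to 9.73 ± 1.05 CPM (SE 0.101, adjusted p = 2.33e-06), the proteoglycan gene Dcn fell 3.73-fold from 388 ± 8.16 to 104 ± 3.40 CPM, and Pdgfrb fell 8.48-fold. Of 3 measured epithelial and intestinal genes none was called by edgeR (0 of 3, and 0 at an unadjusted p under 0.05; Lgals4, the closest, stood at 0.472 ± 0.261 and 0.734 ± 0.180 CPM, adjusted p = 0.273). Of 18 leukocyte markers fixed, 1 was measured, Lyz2, at 0.826 ± 0.208 CPM in controls and 0.259 ± 0.0927 in knockouts. Of 6 melanocyte markers fixed, 2 were measured, and Pmel was at 0.944 ± 0.126 and 1.53 ± 0.180 CPM (adjusted p = 0.0383), a call lost under several alternatives. In lists where no other count is given, the counts adjusted over the list alone were the same.

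**Figure D3:**
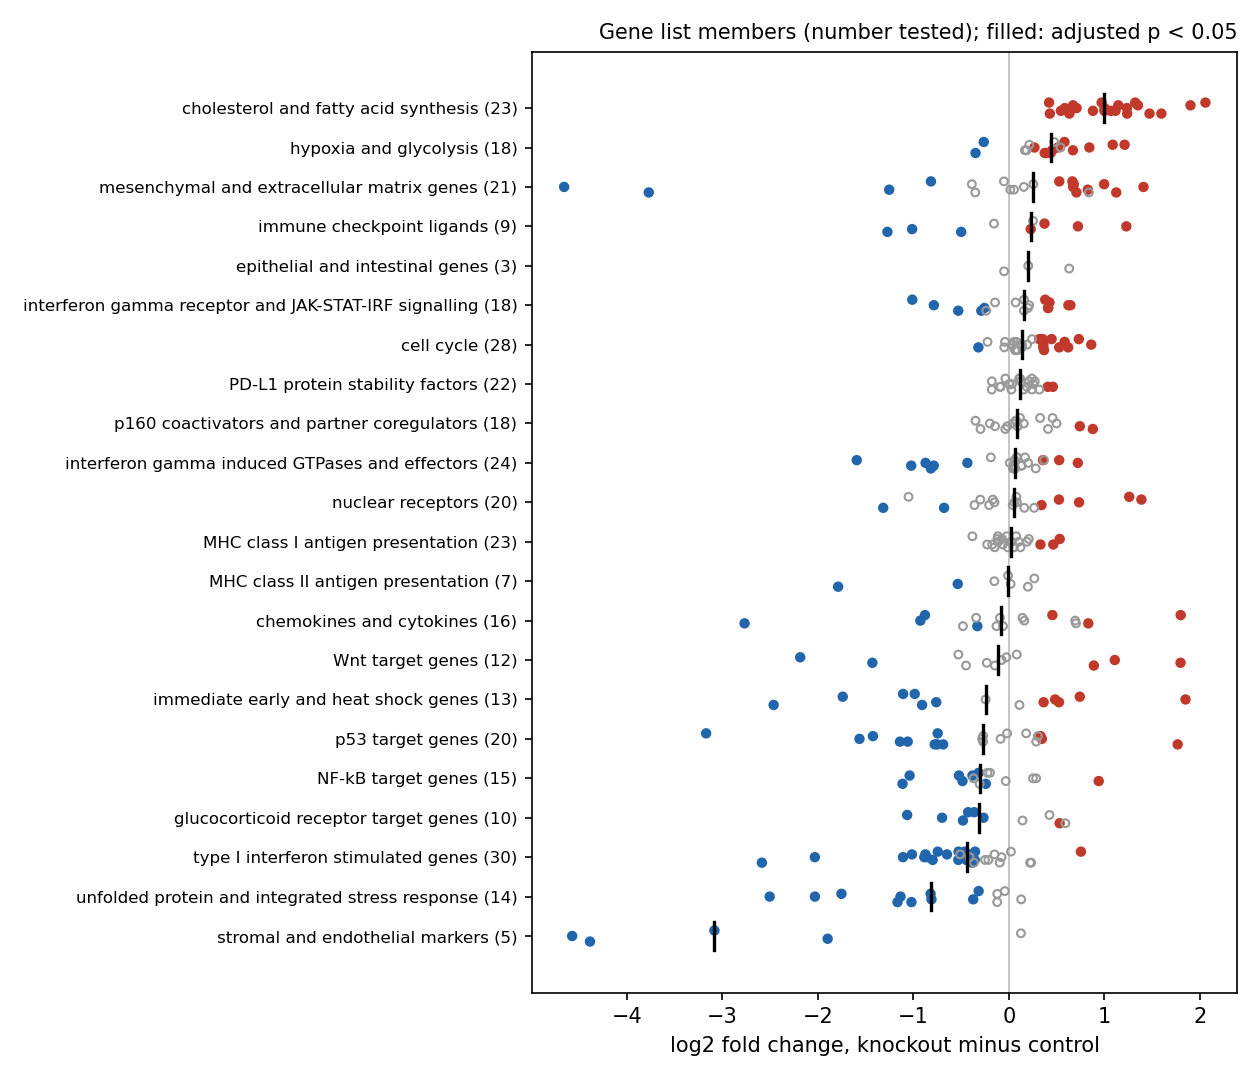
Log2 fold change (knockout minus control) of each measured member of the gene lists with at least 3, sorted by the median, which a black bar marks; filled points passed an adjusted p of 0.05 (red higher, blue lower) and open points did not. All 23 genes of cholesterol and fatty acid synthesis lie to the right of 0. Members at 3 or fewer counts in either group are not drawn, since their fitted changes depend on the prior count.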

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

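The length and GC correction and limma on log2(TPM + 0.1) were chosen after the results were seen. Over all alternatives, the named genes other than Ncoa1 and Cd274, which are described on their own, kept their direction and side of the threshold in 1250 comparisons, lost the call in 40, gained it in 3 (Ncoa2 and Itch without knockout 2, Ncoa3 with the length and GC correction) and turned in 5. The 8 called lists kept theirs in 133 and lost it in 11. Lists that were not called at first are outside this tally, and with no filter on low counts camera called 9 lists. Cd274 stayed lower and called in each alternative run, from -1.35 without control 1 to -1.20 in limma on log2(TPM + 1). The count of genes with at least a 2-fold change was 342 with a mean of at least 10 CPM, where fewer genes were tested, 413 in limma on log2(TPM + 1), 572 on log2(TPM + 0.1) and 374 on log2(FPKM + 1). These fits change the tool, the unit and the filter together, and the smaller pseudocount undid only part of the drop; the cause of the rest was not tested. With the length and GC correction, 3474 genes were called higher, 55.7% of all calls against 48.1%, and Ncoa1 was called at -0.45; the cause was not tested beyond the trend itself. With an estimated inter-gene correlation camera called 0 lists, with 4 at an unadjusted p under 0.05, while fry called 11, or 18 for changes in either direction. Kat2b, Erap1, Lgmn, B3gnt3, Nedd4, Birc3 and Tsc22d3 lost their calls in limma on log2(TPM + 1), in the same direction. In the simulated comparison 49% of the 1.5-fold changes were recovered. Only 163 genes were called there, so the share in the real comparison may differ. Genes that were not called are not shown to be unchanged.

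Ncoa3 turned to 0.0545 in limma on log2(TPM + 1), 0.00627 on log2(FPKM + 1) and 0.0551 on log2(TPM + 0.1); the cause was not tested. Leaving out 1 library at a time, Ncoa3 ran from -0.105 (without knockout 3) to 0.0717 (without knockout 2) and Itch from -0.0231 (without knockout 1) to 0.319 (without knockout 2). In the same way, the genes called higher ranged from 1036 (without control 2) to 4075 (without knockout 2), and those called lower from 1358 (without control 3) to 4133 (without knockout 2). Leaving out knockout 2 therefore moved the number of calls most, from 4157 to 8208. The loss of any control lowered it to between 2406 and 2576, and the loss of knockout 1 or 3 to 3179 or 2850.

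With the replicate number as a block, 2094 genes were called higher and 2301 lower, which held 93.0% of the 4157, 8 lists were called, and Ncoa1 stood at -0.38 and Cd274 at -1.27. Same-numbered control and knockout samples deviated together at correlations of 0.161, 0.261 and 0.0401, and not every sample correlated best with its own number. Knockouts 1 and 3 gave nearly the same values, at 0.161 and 0.186 with control 1 and -0.204 and -0.226 with control 2. Knockout 2 had the opposite sign (-0.210 and 0.261). The correlations thus mostly reflect how knockout 2 differs from the other knockouts. They cannot tell whether same-numbered samples were paired.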

Other observations

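The tests of a mixture of cells and of swapped libraries, the length correlations against the controls and the counts of genes on chromosome X were chosen after the results were seen. Genes outside the fixed lists extended the lower stress response. A set of ATF4 targets, made up of cytosolic tRNA synthetases, amino acid transporters, enzymes of serine and one-carbon metabolism and other known targets, was written down after Chac1 and Trib3 had been seen but before the values of the set. Of 33 measured, 0 rose, 30 fell and 3 were not called, with a median log2 fold change of -0.86 (camera p = 4.52e-15; p = 0.0279 with an estimated correlation). Of these, Mthfd2, a mitochondrial folate enzyme, fell from 280 to 130 CPM, the cystine and leucine transporter subunit gene Slc3a2 from 915 to 447 CPM, and Gars, the glycyl-tRNA synthetase gene, from 1039 to 572 CPM. The mitochondrial tRNA synthetases, which served as a comparison, had a median of -0.03, with 2 of 17 higher, 5 lower and 10 not called. A hypothesis is that ATF4 activity was lower in the knockout cells, which is consistent with the median of -0.86. Whether the cells differed in amino acid supply, density or time in culture is not stated, and such differences could give the same pattern.

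Genes of 5 CPM or more in the controls that were at 3 counts or fewer in the 3 knockouts together numbered 5, and none went the other way (0 genes by counts). They were Arhgap6, Gm773, Lin7b, Mageb4 and Tspan6. Chromosome X holds 4 of the 5, against 298 of the 9909 genes that reached 5 CPM in the controls.

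Knockout and control also differed by chromosome, where the median log2 fold change was 0.24 on chromosome 16 (317 genes, 120 risen and 21 fallen), -0.17 on chromosome 6 (466 genes, 33 risen and 163 fallen) and 0.17 on X, and in genes shuffled over the chromosomes the medians never spread as widely (permutation p = 1e-04, the smallest that 10000 permutations can give). The shift on chromosome 16 was present in knockouts 1, 2 and 3 (0.25, 0.21 and 0.23) and in each full window of 50 genes along it, from 0.17 to 0.33. Chromosome 6 was lower in all 3 knockouts (-0.16, -0.20 and -0.17), with windows from -0.39 (128356999 to 146634605) to 0.03, whereas X was at 0.21, 0.02 and 0.20 and so nearly level in knockout 2. Removing the length and GC trends left 0.29 on chromosome 16 and -0.14 on chromosome 6, which argues against those trends as the source. A candidate explanation is a difference in copy number, or in the clone of origin, between the control and knockout populations, but shared regulation of neighbouring genes, which shuffling ignores, and an effect of SRC-1 loss itself stay open, since each population is one arm of the design.

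The deviation of knockout 2 from the mean of knockouts 1 and 3 had an SD of 0.465 on the log2 scale, against 0.182 from their own spread, and it fell with transcript length (Spearman correlation -0.62 across 11319 genes, which are not independent) and rose with GC content (0.52). Length and GC accounted for 55.6% of the excess variance (interval 53.1 to 57.9), so such a trend may be a large part of what parts these libraries, though the SD without it was still 0.332 and the remaining 44.4% has no tested source. The trend is not in knockout 2 alone: against the controls, the correlation with length was -0.20 in knockout 2 and 0.37 and 0.31 in knockouts 1 and 3, where each control against the others gave -0.24 to 0.20, and the log2 fold change of the whole comparison correlated with length at 0.19. These correlations do not compare the sizes of the trends. The SD against the controls was 0.680, 0.652 and 0.661 in knockouts 1, 2 and 3, and 0.180 to 0.198 in the controls. The trend held 8.55%, 6.81% and 5.81% of that variance in knockouts 1, 2 and 3, and 1.71% to 5.40% in the controls. It was thus of similar size in all 3 knockouts and larger than in the controls, with the opposite direction in knockout 2. Control cells mixed into that library were excluded as the source: over 33 genes at least 8-fold lower in the other knockouts, knockout 2 held a median of 0% of the control level (interval -0.65 to 0.664), where its place on the first principal component would need 13.5%. Its genotype label, which reads SRC-2, leaves a separate clone or another target open in part. Ncoa2 was below each control in this library, also with the length and GC trends removed (32.5 against 39.5 to 41.1 CPM). Such a dip was not particular to Ncoa2, however. With the trends removed, Itch was also below each control there (63.1 against 69.8 to 72.2 CPM). Without that correction, the p160 coactivators and partners lay a median of 0.45 lower in knockout 2 than in knockouts 1 and 3. Ncoa1 was lowest in knockout 2 too, and 1 library allows no test. Knockout 2 shared the losses of the 33 genes and the shift on chromosome 16 (0.21, against 0.25 and 0.23) with knockouts 1 and 3. These values argue against a line that differs in both origin and target, whereas either difference alone stays open.

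The level of Ncoa1 in the knockout was close to that of the controls. Reads shared with Ncoa2 and Ncoa3 would leave fractions in estimated counts, and the decimal parts of the 6 Ncoa1 counts added up to 0% of their total. A swap of single libraries between the groups is argued against as well, since 0 libraries correlated better with a library of the other group than with each of their own, a count that cannot detect an exchange of both groups as a whole. With the length and GC trends removed, Ncoa1 was at 18.9 ± 0.504 CPM in controls and 14.7, 12.0 and 14.7 CPM in knockouts 1, 2 and 3 (log2 fold change -0.45), so those trends may have hidden part of a modest fall. An edit that changes the protein and leaves most of the mRNA stays open, as gene-level counts do not show the edited site. A knockout in part of the cells, with enough control-like cells left to hold Ncoa1 at this level, is argued against by fuller losses elsewhere. Col6a3 fell from 204 to 9.73 CPM, Gadd45a from 264 to 29.3 CPM, and Mageb4 from 474 counts to 0. Control-like cells would still express these genes. Unedited cells that had lost them as well stay open.

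The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4157 called genes, 830 called genes with at least a 2-fold change and 8 called lists, and was in each case the 1 split with a result that large. The highest of the other splits were 0, 0 and 6. Each other split mixes libraries of both arms, so the difference between the arms adds to the spread within its groups. Its 0 called genes are therefore no baseline for the real split. Camera still called 1 to 6 lists in the other splits, where no gene was called, beside 8 in the real one.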
